A study of Mus musculus with 71 samples.

How the data were processed

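The series measures gene expression and chromatin in mouse embryonic stem (ES) cells. Per the labels, 9 libraries are polyA RNA sequencing of C57BL/6 cells: 3 of wild type (WT), 3 of an Ezh1/Ezh2 double knockout (dKO) and 3 labelled as an EZH2 rescue, described as re-expressing wild-type EZH2. The other 62 samples are chromatin immunoprecipitation (ChIP). Of these, the list of Suz12 peaks from wild-type 129B6F1 cells was used and 61 samples were not analysed here. 2 of the 61 have titles and antibody labels that name different antibodies and were put in no group. All groups and comparisons follow the labels.

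The RNA values are counts of reads per gene, deposited by the authors without normalization as whole numbers. Per the submitters' processing notes, reads were handled with Trimmomatic, STAR 2.4.0 and HTSeq on the mm10 build, and per the labels' protocols the libraries were made with the TruSeq RNA Library Prep Kit v2, which does not mark strand. The counting mode and the gene annotation are not given in the sources used here. Overlapping genes and antisense partners can therefore not be told apart in these counts, and genes with near-identical copies, such as Tuba3a and Tuba3b, are uncertain. The Suz12 file holds other values, deposited by the authors as peak coordinates only, with no score. The peak caller, its threshold and whether samples were pooled are not given in the sources used here. Coordinates are given 1-based on mm10.

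The count tables name 24222 genes and contain 0 entries that name no gene. A table of GRCm38.p6 genes, the assembly that mm10 is built from, placed 22859 of them by symbol and 1205 by synonym, and 158 were not matched. That table has no strand, so transcription start sites were not known. A gene was counted as a Suz12-peak gene when a peak overlapped the window within 1 kb of either end of the gene by at least 1 base, in place of the start site alone that the design named.

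Total counts per library were 15018882, 22249263 and 19912881 in WT, 12457622, 22043118 and 23549185 in dKO, and 36009529, 22228851 and 23761980 in rescue. A count of 0 allows a level of up to 0.0833 CPM in the deepest and 0.241 CPM in the shallowest library, taking 3 counts as the limit and the total counts, before TMM, as the library size. Intervals and limits cover counting error only. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom between 2.21 and 23.9 over genes, so no library was treated as a repeat of another. Nothing in the labels says that replicates come from separate cultures, so p-values measure only the spread between these samples, which may be technical.

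Differential expression was computed with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, glmQLFit with robust estimation and glmQLFTest, in 1 fit of all 9 libraries with a mean per group and 6 residual degrees of freedom. After the filter 14145 genes were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over these genes, and "rose" or "fell" is used only of called genes. All tests were two-sided. Values per gene are CPM (the unit of edgeR's cpm function) scaled by TMM, as mean ± SD over 3 libraries, and log2 fold changes with the standard error (SE) of the fit.

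21 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They hold PRC2 core and accessory genes, PRC1 genes, H3K27 demethylases with acetyltransferases and other writers, Hox genes, naive and formative pluripotency genes, markers of mesoderm, endoderm, neural cells, trophoblast, germline and fibroblasts, other developmental transcription factors, imprinted genes, CDK inhibitors with p53 targets, 2-cell-like genes, MAPK and Wnt response genes, stress genes and housekeeping genes. Each list with at least 3 tested members was compared with the other genes by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 20 lists tested. The alternatives were camera with an estimated correlation and fry, which asks whether the members of a list move on balance in 1 direction and does not compare the list with other genes. Of the 2-cell-like list only Tmem92 and Eif1a passed the filter, so it was not tested.

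The genes named are Ezh1, Ezh2, Eed and Suz12, then per comparison the 8 largest changes each way among called genes whose 3 libraries of each group did not overlap and whose mean was at least 2 CPM, leaving out predicted-gene identifiers, and from each list up to 3 members with the smallest adjusted p and up to 1 that did not pass. Suz12-peak genes were compared with the other placed genes by Fisher's exact test, by camera and by the median of 10000 random lists matched on mean expression. Overlaps between comparisons that share libraries were set beside the overlap of independent lists, and the covariance and correlation of fold changes beside 20 simulations of unchanged groups. Medians per chromosome and per 10 Mb were taken over genes with a mean of at least 5 CPM for single libraries and over all tested genes for comparisons.

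The main test was tried on simulated data in which 200 genes changed by known folds, 50 at each of 4 sizes. For dKO against WT, with 13900 genes, 14% of 1.25-fold, 68% of 1.5-fold, 78% of 2-fold and 100% of 4-fold changes were called, and 7.8% of calls were false. For rescue against dKO, with 13922 genes, the shares were 28%, 62%, 84% and 100%, and 5.52% of calls were false. For rescue against WT, with 13935 genes, they were 18%, 66%, 86% and 88%, and 9.15% of calls were false. These shares hold for few changes, with as many genes raised as lowered. In the data 9151 of 14145 genes were called in dKO against WT, so the shares do not gauge the real calls.

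The alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0 (Wald test) and limma-voom, no filter or a mean of at least 2 CPM, the 2 compared groups alone, the replicate number as a further term, a 2-fold minimum, each library left out in turn, peaks within 5 kb or anywhere in the gene, the peaks above the median width, and genes matched on expression. Leaving out chromosomes 3 and 14 was added after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.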

Results

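RNA from mouse ES cells was sequenced in 3 groups of 3 libraries: wild type (WT), cells labelled as a double knockout of Ezh1 and Ezh2 (dKO), and cells labelled as an EZH2 rescue (rescue). Ezh1 and Ezh2 encode the alternative methyltransferase subunits of Polycomb repressive complex 2 (PRC2), which methylates H3K27. All cells were kept on gelatin in 2i, a medium that holds ES cells in the naive state of pluripotency. Libraries held between 12457622 and 36009529 counts, and 14145 genes passed the filter. Correlations of log expression across genes were 0.986 to 0.997 between replicates, 0.930 to 0.934 between WT and dKO, and 0.968 to 0.972 between WT and rescue. The first principal component took 68.7% of the variance and placed dKO at 78.7 to 87.8 against -44.7 to -40.6 for the other libraries. The second, with 21.9%, placed WT at -42.62 to -38.97 and rescue at 40.67 to 42.15. On it dKO replicate 3 stood at 12.3 while dKO replicates 1 and 2 stood at -7.46 and -6.42. A list of 7480 Suz12 peaks from wild-type 129B6F1 ES cells was also used.

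The targeted genes were read first in every library. Ezh1 (chromosome 11, 101191115 to 101226463) was at 53.4, 48.4 and 47.9 CPM in WT, at 2.34, 1.83 and 1.80 CPM in dKO, and at 2.89, 2.33 and 3.42 CPM in rescue. Ezh2 (chromosome 6, 47530274 to 47595270) was at 308, 314 and 310 CPM in WT, at 192, 191 and 214 CPM in dKO, and at 555, 576 and 549 CPM in rescue. Against WT, Ezh1 fell by 4.68 ± 0.138 (log2 fold change, SE) in dKO, and Ezh2 fell by 0.64 ± 0.058 in dKO and rose by 0.85 ± 0.057 in rescue, with edgeR Benjamini-Hochberg adjusted p = 2.35e-10, 1.4e-06 and 4.51e-07. Gene-level counts cannot show the deletion of single exons, nor separate an introduced EZH2 transcript from the native one, so the Ezh2 level checks the labels only in part. Eed, which binds methylated H3K27, fell from 239 ± 7.46 CPM in WT to 131 ± 11.8 in dKO (SD, n = 3 libraries) and was 271 ± 7.67 in rescue. Suz12, the scaffold subunit, was at 459 ± 18.2, 548 ± 88.2 and 761 ± 39.99 CPM (SD, n = 3). Its rise in dKO, a log2 fold change of 0.26 with edgeR Benjamini-Hochberg adjusted p = 0.0301, was lost without WT replicate 1 (0.0806), WT replicate 2 (0.103) or dKO replicate 3 (0.0699, with the log2 fold change at 0.12) and when only the 2 groups entered the fit (0.0534). The rise of Eed in rescue against WT, 0.18 with edgeR Benjamini-Hochberg adjusted p = 0.0392, was lost without any 1 of the WT libraries (0.0913, 0.0611 and 0.114), without any 1 of the rescue libraries (0.0713, 0.107 and 0.0697) and without chromosomes 3 and 14 (0.0575).

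**Figure D1:**
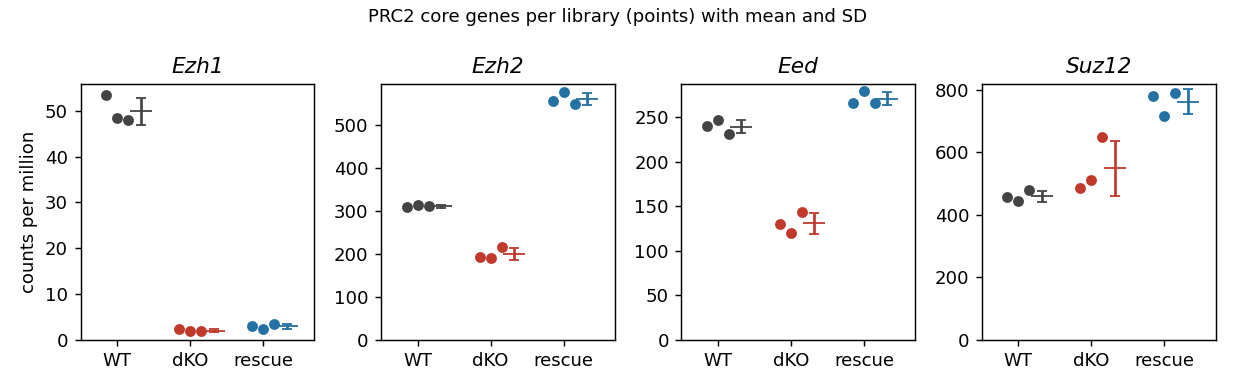
CPM of Ezh1, Ezh2, Eed and Suz12 in each library (points) with the group mean and SD (bars, n = 3). Ezh1 lies between 47.9 and 53.4 in WT and at most 3.42 in the other 6 libraries, and Ezh2 is lowest in dKO and highest in rescue.

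Comparing dKO with WT asks which genes differ in the cells labelled as lacking both methyltransferases. Among the genes with the largest gains, Tbx5, a heart transcription factor, was at 7.72 ± 1.02 CPM in dKO and 0.108 ± 0.0967 in WT (SD, n = 3), and Myh6, the cardiac myosin heavy chain, at 5.91 ± 0.806 against 0.0622 ± 0.108. Hoxa10 rose by 5.86, the proteoglycan Cspg4 by 5.63 and the actin-binding Coro2a by 5.38 on the log2 scale. Hpcal4, a neuronal calcium sensor, had 378 counts in the 3 dKO libraries and 1 in the 3 WT libraries (ratio 372, exact 95% interval 66.4 to 14700), and the integrin Itga11 had 533 and 2 (ratio 263, 72.3 to 2170). Ly6a was at 7.02 ± 5.42 CPM in dKO and 0.0786 ± 0.0512 in WT, with a wide spread among dKO libraries. Among genes that fell, the log2 fold change was -5.48 for Hdhd1a, -5.41 for the GTPase Rac2, -4.85 for Fgf17, -4.27 for Csrnp3 and -4.23 for the T-cell co-stimulator Cd80. In all, 4769 genes rose and 4382 fell, and 2707 and 621 of them by over 2-fold. Over all tested genes, called or not, the 2 groups did not overlap for 68.0%, where chance gives 10%.

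The Hox, mesoderm, endoderm and germline lists were called by camera in dKO against WT with either correlation. Tested were 30 of 39 listed Hox genes, 19 of 26 mesoderm, 17 of 22 endoderm and 22 of 22 germline genes. Of the lists below, 19 of 31 neural genes and 25 of 38 other transcription factors were tested. A gene near 0 in WT can pass the filter through dKO alone, so shares that rose hold for tested members only. Of 30 tested Hox genes, the transcription factors of body-axis patterning, 28 rose, 0 fell and 2 did not pass, with a median log2 fold change of 2.85. Hoxc10 went from 0.601 ± 0.0804 to 10.1 ± 0.890 CPM and Hoxd9 from 0.622 ± 0.0646 to 5.49 ± 0.537 (SD, n = 3), while Hoxd10 had 68 counts in dKO and 0 in WT, at least 20.3-fold higher with 3 counts over the group as the limit. Of 19 mesoderm genes 16 rose, 2 fell and 1 did not pass (median 2.74), with Tbx20 up by 3.65 and Isl1 by 2.88, and Bmp2 at 0.56 without passing. Of 17 endoderm genes 15 rose, 1 fell and 1 did not pass (median 2.43). Among them were the basement-membrane collagens Col4a1 (3.73) and Col4a2 (12.1-fold) and the endocytic adaptor Amn (4.25), while the laminin Lama1 stood at -0.05 and did not pass. Of 22 germline genes 18 rose, 1 fell and 3 did not pass (median 1.62), with the piRNA factor Piwil2 up by 2.78 and the sperm ADP/ATP carrier Slc25a31 by 3.97. Tuba3b, up by 4.90, shares near-identical sequence with Tuba3a and is uncertain. Against other genes, limma's camera gave Benjamini-Hochberg adjusted p = 2.53e-09 for Hox, 0.000337 for mesoderm, 2.39e-06 for endoderm and 2.22e-10 for germline genes. With an estimated correlation the adjusted p was 0.0102, 0.0498, 0.0102 and 0.00591. Counts adjusted over the list alone were the same but for 19 germline genes higher.

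Of 19 neural genes 13 rose, 3 fell and 3 did not pass (median 1.78), with the progenitor filament Nes up by 2.53, Irx3 by 2.65 and Olig2 by 1.78, and Sox1 at -0.29 without passing. Of 25 other developmental transcription factors 21 rose, 2 fell and 2 did not pass (median 2.56). Barx1 rose by 5.79 and Tbx15 by 3.29, whereas Ebf1, a B-cell and neuronal factor, fell by 2.92. Of 10 fibroblast markers 8 rose, 1 fell and 1 did not pass (median 2.65), with the surface protein Thy1 up by 4.08 and fibrillin Fbn1 by 3.80, but Vim, the most abundant of those named in WT at 343 ± 10.1 CPM, fell to 20.7 ± 8.26 (SD, n = 3). Camera gave adjusted p = 0.0026, 2.67e-05 and 0.00158 for these 3 lists by Benjamini-Hochberg. The calls were lost with an estimated correlation, with adjusted p = 0.0881 for neural genes, adjusted p = 0.112 for the other transcription factors and adjusted p = 0.0773 for fibroblast markers, and the fibroblast call also without dKO replicate 3 (adjusted p = 0.0692). Of 13 trophoblast genes 7 rose, 2 fell and 4 did not pass (median 1.84, camera Benjamini-Hochberg adjusted p = 0.0577). The keratin Krt18 rose by 3.17, Esx1 by 1.84 and Krt8 to 6.49-fold of WT. That list did pass without WT replicate 1 (0.0449), dKO replicate 1 (0.0283), 2 (0.0182) or 3 (0.0204) and with no filter (0.0282). Adjusted over the list alone, 22 of the other transcription factors and 9 fibroblast markers rose, and the remaining counts were the same.

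Genes of the Polycomb machinery and of pluripotency moved the other way or in both directions. Of the 6 PRC2 core genes 5 fell and Suz12 alone rose (median -0.76), Rbbp7 falling by 1.07 (camera Benjamini-Hochberg adjusted p = 1.93e-05, adjusted p = 0.0773 with an estimated correlation). That list holds the targeted genes Ezh1 and Ezh2 and was not tested without them. Of 26 naive and general pluripotency genes 17 fell, 5 rose and 4 did not pass (median -0.33), with Lin28a at 58.3 ± 1.88 against 130 ± 8.63 CPM, Klf5 at -1.15 and Utf1 up by 1.10 (camera Benjamini-Hochberg adjusted p = 0.00664, adjusted p = 0.0773 with an estimated correlation). Of 8 PRC2 accessory genes 3 rose, 1 fell and 4 did not pass (camera Benjamini-Hochberg adjusted p = 0.338). AU022751, the mouse counterpart of the PRC2 inhibitor EZHIP, went from 1.36 ± 0.107 to 28.7 ± 3.08 CPM (SD, n = 3), in a segment of chromosome X whose median in the dKO libraries was 0.75, 0.81 and 0.71, and Mtf2 fell by 0.79. Of 20 PRC1 genes 8 rose, among them the chromobox gene Cbx8 (1.75), 8 fell, among them Phc1 (-1.16), and 4 did not pass, with Pcgf1 at -0.21 (adjusted p = 0.879 by camera and Benjamini-Hochberg, pointing up with a mean of 0.24 where the median was -0.08). Of 9 H3K27 demethylase, acetyltransferase and other writer genes 4 fell, 0 rose and 5 did not pass, the demethylase Kdm6a falling by 0.75 (adjusted p = 0.272 by camera and Benjamini-Hochberg). Adjusted over the list alone, the counts were the same for these 5 lists.

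The remaining lists did not differ from other genes by camera in dKO against WT. Of 28 imprinted genes 14 rose, 10 fell and 4 did not pass (Benjamini-Hochberg adjusted p = 0.451), including Sfmbt2 at 489 ± 25.03 CPM in dKO against 42.8 ± 3.09 in WT (SD, n = 3), Rian at -2.33 and Peg3 at -1.42. Of 11 formative pluripotency genes 6 rose, 3 fell and 2 did not pass (0.879), with Pou3f1 at 1.78 and Zic2 at -1.07. Of 16 Wnt response genes 6 rose, 6 fell and 4 did not pass (0.819), Nkd1 at 2.62 and Sp5 at -2.02, and camera pointed down where the median (0.05) and the mean (0.23) were above 0. Of 12 MAPK response genes 3 rose, 4 fell and 5 did not pass (0.451), Dusp6 at -1.17 and Ier3 at 1.14, with a median of -0.26 and a mean of 0.02. Of 15 CDK inhibitors and p53 targets 3 rose, 8 fell and 4 did not pass (0.338), Cdkn1c at 3.19 and Mdm2 at -0.47, with a median of -0.23 and a mean of 0.09. Of 16 stress genes 8 rose, 6 fell (7 adjusted over the list alone) and 2 did not pass (0.687), Junb at 1.72 and Gadd45a at -1.47, and camera pointed down with the median at 0.13. Of 14 housekeeping genes 1 rose, B2m by 1.42, 6 fell and 7 did not pass (0.306). Adjusted over the list alone, the other counts were the same.

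**Figure D2:**
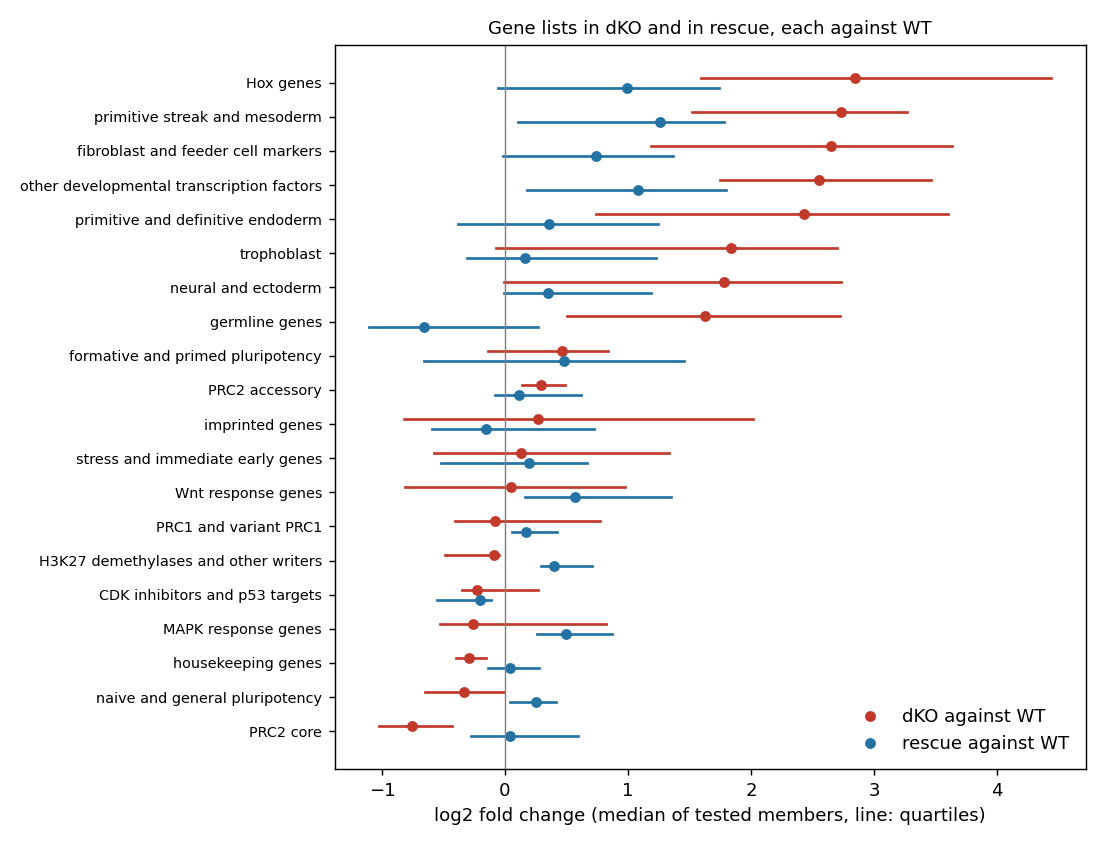
Median log2 fold change of the tested members of each of 20 gene lists (points) with quartiles (lines), for dKO and for rescue, each against WT. Hox genes have a median of 2.85 in dKO and 0.99 in rescue, and germline genes 1.62 and -0.66.

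Suz12 peaks were then used to ask whether genes bound by PRC2 in wild-type cells behave apart from others. The 7480 peaks had a median width of 1032 bp (281 to 16063) and covered 10.4 Mb, and 58.1% lay within 1 kb of an end of a protein-coding gene, where peaks shifted at random gave 7.22% on average over 20 shifts. The widest ran from 96289430 to 96305492 on chromosome 11, over Hoxb5, Hoxb6 and Hoxb7. Peaks covered 60.2% of the Hoxa cluster (chromosome 6, 52155367 to 52260880), 49.5% of Hoxd (chromosome 2, 74668225 to 74765142), 30.9% of Hoxb (chromosome 11, 96194316 to 96368254) and 25.04% of Hoxc (chromosome 15, 102921131 to 103036856). Of the 3692 tested genes with a peak 58.1% rose in dKO, against 25.1% of 10403 without (odds ratio 4.14, 95% interval 3.82 to 4.48, Fisher's exact test p = 6.26e-280), and 16.4% against 36.2% fell (odds ratio 0.346, 0.314 to 0.381, Fisher's exact test p = 3.32e-119). Their median log2 fold change was 0.57, against -0.09 for other genes (camera p = 6.81e-13, p = 0.00318 with an estimated correlation), and 1.02 when only peaks above the median width counted. With a mean of at least 2 CPM it was 0.38. In rescue against dKO it was -0.57 against 0.06 (camera p = 5.56e-10, p = 0.00617 with an estimated correlation), -0.86 for the wider peaks. In rescue against WT it was 0.06 against -0.01 (camera p = 0.312), 0.13 for the wider peaks, although 28.7% of peak genes against 26.2% of others rose (odds ratio 1.14, 1.04 to 1.24, Fisher's exact test p = 0.00285). Genes are not independent replicates, the peaks come from another strain, and 76.1% of peak genes but 54.2% of other genes passed the expression filter.

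**Figure D3:**
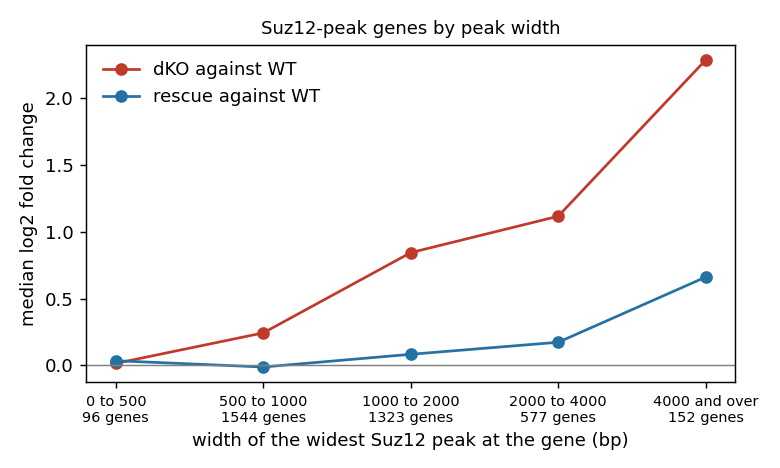
Median log2 fold change against WT of the genes in each class of Suz12 peak width (points), for dKO and for rescue. The classes, chosen after the data were examined, hold 96, 1544, 1323, 577 and 152 genes, from under 500 bp to 4000 bp and over.

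Comparing rescue with dKO asks what differs in the cells labelled as an EZH2 rescue. Rac2, Hdhd1a and Fgf17, which fell in dKO against WT, were among the genes with the largest gains and rose by 5.49, 5.40 and 4.87 on the log2 scale. The serotonin receptor Htr5a was at 15.97 ± 0.982 CPM in rescue and 0.363 ± 0.250 in dKO, and the homeobox gene Nkx1-2 at 30.6 ± 2.21 and 1.64 ± 0.0922 (SD, n = 3), and the ETS factor Etv1 rose by 4.51. The largest losses were the neural homeobox gene Dbx2 at -6.15, Tex101 at -5.96, Itga11 at -5.92, Paqr5 at -5.88, Tuba3b (uncertain) at -5.87, the water channel Aqp8 at -5.59, Sept4 at -5.53 and the lipase Pnliprp2 at -5.43. In all, 4534 genes rose and 5407 fell, 712 and 2820 of them by over 2-fold. The groups did not overlap for 71.7% of all tested genes, where chance gives 10%.

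In rescue against dKO, the Hox, germline and naive pluripotency lists were called by camera with either correlation. Of 30 Hox genes 27 fell, 1 rose and 2 did not pass (median -1.91), Hoxa10 going from 17.0 ± 2.98 to 0.977 ± 0.293 CPM and Hoxb13 from 20.5 ± 2.49 to 2.16 ± 0.142 (SD, n = 3). Of 22 germline genes 20 fell, 1 rose and 1, the synaptonemal gene Sycp3 at -0.16, did not pass (median -2.31), with the cohesin subunit Smc1b at -3.70 and Tuba3a (uncertain) at -3.13. Of 26 naive pluripotency genes 19 rose, 3 fell and 4 did not pass (median 0.51), led by Lin28a (1.77), Zfp57 (1.59) and Sall4 (0.99). Camera gave Benjamini-Hochberg adjusted p = 1.16e-05 for Hox genes, 3.19e-14 for germline genes and 1.16e-05 for naive genes. With an estimated correlation the adjusted p was 0.034, 0.00243 and 0.0322. Of 17 endoderm genes 14 fell (15 adjusted over the list alone), 1 rose and 2 did not pass (median -2.18), with Gata6 at -4.66 and Col4a2 at -3.09 (camera Benjamini-Hochberg adjusted p = 0.000241, adjusted p = 0.0511 with an estimated correlation). All 6 PRC2 core genes rose (median 0.66, with the targeted Ezh1 and Ezh2 among them and no test without these, camera Benjamini-Hochberg adjusted p = 0.000997, adjusted p = 0.155 with an estimated correlation). Ezh1 rose only from 1.99 ± 0.301 to 2.88 ± 0.540 CPM (SD, n = 3), with overlapping libraries, and was at 49.9 CPM in WT. Of 9 H3K27 demethylase, acetyltransferase and other writer genes 8 rose, 0 fell and 1 did not pass (9 higher adjusted over the list alone), with Kdm6a at 0.97 and Setd2, in a segment of chromosome 9 raised as a whole in rescue, at 0.86 (camera Benjamini-Hochberg adjusted p = 0.00967, adjusted p = 0.371 with an estimated correlation). For the other 4 lists the counts adjusted over the list alone were the same.

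In rescue against dKO 5 further lists were called by camera with the preset correlation but not with an estimated correlation. Of 12 MAPK response genes 7 rose, 2 fell and 3 did not pass (median 0.77), with the ETS factor Etv5 at 246 ± 9.68 against 80.2 ± 10.1 CPM (SD, n = 3), the feedback inhibitor Spry4 up by 3.91, Dusp6 by 1.60 and Ier3 at -0.17 without passing (camera Benjamini-Hochberg adjusted p = 0.0153, adjusted p = 0.208 with an estimated correlation). Of 16 Wnt response genes 8 rose, 3 fell and 5 did not pass (median 0.52), with Sp5 up by 4.05, T by 2.81 and Nkd1 down by 1.48 (camera Benjamini-Hochberg adjusted p = 0.0213, adjusted p = 0.128 with an estimated correlation). The Wnt call was lost with a mean of at least 2 CPM (adjusted p = 0.0656). Of 25 other developmental transcription factors 17 fell, 5 rose and 3 did not pass (median -1.64), with Tbx15, on chromosome 3 (median -0.43), at -2.73 and Barx1 going from 5.32 ± 0.531 to 0.311 ± 0.111 CPM (SD, n = 3), while Ebf1 rose by 2.46 (camera Benjamini-Hochberg adjusted p = 0.0153, adjusted p = 0.267 with an estimated correlation). Of 10 fibroblast markers 7 fell, 1 rose and 2 did not pass (median -1.31), Thy1 at -4.17 and Col6a2 at -4.31, with Col5a1 at -0.07 without passing (camera Benjamini-Hochberg adjusted p = 0.0295, adjusted p = 0.208 with an estimated correlation). Of 28 imprinted genes 14 fell, 4 rose and 10 did not pass (median -0.37), Sfmbt2 at -4.07 and Smoc1 at -2.60 (camera Benjamini-Hochberg adjusted p = 0.0295, adjusted p = 0.208 with an estimated correlation). Without dKO replicate 3 the last 3 lists were no longer called (adjusted p = 0.076, 0.188 and 0.0951), nor the transcription factors without chromosomes 3 and 14 (0.0639) or the imprinted genes with no filter (0.0716). Counts adjusted over the list alone were the same for these 5 lists.

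Other lists were not called in rescue against dKO. Of 19 mesoderm genes 10 fell, 3 rose and 6 did not pass (camera Benjamini-Hochberg adjusted p = 0.19), Tbx20 at -3.17 while Eomes, in a segment of chromosome 9 raised as a whole in rescue, rose by 1.87. Of 19 neural genes 10 fell, 3 rose and 6 did not pass (0.19), Irx3 at -3.65 while the neuronal tubulin Tubb3 rose by 2.23. Of 13 trophoblast genes 9 fell, 2 rose and 2 did not pass (0.105), and this list was called without dKO replicate 2 (0.0358) and with no filter (0.0477). The others were PRC2 accessory genes (2 higher, 2 lower, 4 not passing, 0.526), PRC1 genes (7, 8 and 5, 0.196), formative genes (3, 3 and 5, 0.454, with 2 higher adjusted over the list alone), CDK inhibitors and p53 targets (4, 9 and 2, 0.777), stress genes (6, 6 and 4, 0.265) and housekeeping genes (6, 2 and 6, 0.133). AU022751 fell to 1.26 ± 0.267 CPM from 28.7 ± 3.08 (SD, n = 3) and Phf19 stood at -1.60, while Phc1 rose by 1.39, the cadherin Cdh2 by 2.10, Hmox1 by 0.84 and Polr2a by 0.95. PRC2 accessory genes had a median of 0.18 and a mean of -0.52, stress genes a median of 0.12 and a mean of -0.38 where camera pointed up, and PRC1 genes a median of -0.04 where camera pointed up. Adjusted over the list alone, the counts were otherwise the same for these lists.

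The 2 comparisons were joined to ask how many genes changed in dKO moved back in rescue. Of the 4769 genes that rose in dKO 3715 (77.9%) fell in rescue against dKO, and of the 4382 that fell 2834 (64.7%) rose. Among genes over 2-fold higher in dKO 2394 of 2707 (88.4%) fell again, and with a Suz12 peak 1793 of 2144 (83.6%), against 1910 of 2609 (73.2%) without, a difference that was not tested. Against WT, 1706 of the genes that rose in dKO remained higher in rescue, 831 were now lower and 2232 were not called. Of those that fell, 1788 remained lower, 779 were now higher and 1815 were not called. Lists drawn independently would share 1823 and 1405 genes in the 2 reversals, and 1279 and 1195 for genes still on the dKO side of WT. Simulated unchanged groups give almost no calls, so their overlaps cannot gauge these counts. Across genes, the covariance of the fold changes was -1.19 between the first 2 comparisons (simulated -0.0206) and 0.374 between dKO and rescue, each against WT (simulated 0.0218). The covariance grows with the size of the changes. The correlation was -0.795 for the first pair (simulated mean -0.509). For the second it was 0.380, below the simulated 0.507 to 0.555. With 3 shared libraries no split leaves 2 in each part, so part of each overlap may come from the shared libraries.

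Comparing rescue with WT asks where the cells labelled as an EZH2 rescue differ from WT, whether or not dKO differed there. Among the genes with the largest gains, the bHLH inhibitor Id3 was at 26.6 ± 2.84 CPM against 1.02 ± 0.227 in WT, Spry4 at 5.62 ± 0.863 against 0.215 ± 0.0154, and Dnmt3l, the cofactor of de novo DNA methyltransferases, at 212 ± 16.8 against 17.2 ± 1.32 (SD, n = 3). The immune regulator Aire rose by 4.17, Crmp1 by 3.67, Cemip by 3.61 and the kinase scaffold Ksr2 by 3.50. Hpcal4 had 44 counts in rescue and 1 in WT (ratio 30.7, exact 95% interval 5.23 to 1240). Beside Ezh1, the largest losses were Efhc2 at -4.53, Dmrtc2 at -3.45, Dpep3 at -3.34, the immediate early gene Fos at -3.17 and Slfn9 at -3.15. Ptprtos, an antisense transcript of Ptprt, and the multi-copy gene Xlr4a, at -3.24 and -3.03, are uncertain. In all, 3794 genes rose and 3859 fell, 910 and 919 by over 2-fold. The groups did not overlap for 65.3% of all tested genes, where chance gives 10%.

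In rescue against WT camera called 11 lists with the preset correlation and 0 with an estimated correlation. Of 16 Wnt response genes 10 rose, 1 fell and 5 did not pass (median 0.57), with Sp5 at 34.4 ± 2.55 against 8.42 ± 0.680 CPM (SD, n = 3), T (brachyury) up by 1.70 and Cdx1 by 1.23 (camera Benjamini-Hochberg adjusted p = 0.00455, adjusted p = 0.0939 with an estimated correlation). Of 19 mesoderm genes 10 rose (11 adjusted over the list alone), 0 fell and 9 did not pass (median 1.26), with Eomes at 46.0 ± 2.61 against 14.9 ± 0.729 CPM (SD, n = 3; camera Benjamini-Hochberg adjusted p = 0.00455, adjusted p = 0.0939 with an estimated correlation). Of 12 MAPK response genes 8 rose (9 adjusted over the list alone), 1 fell and 3 did not pass (median 0.50), Ier3 by 0.98 and Etv5 by 0.52 (camera Benjamini-Hochberg adjusted p = 0.0279, adjusted p = 0.266 with an estimated correlation). Of 26 naive pluripotency genes 17 rose, 3 fell and 6 did not pass (median 0.26), Zfp57 by 1.08 and Tdgf1 by 1.05, while Dppa3 fell by 1.43 (camera Benjamini-Hochberg adjusted p = 0.02, adjusted p = 0.147 with an estimated correlation). Of 19 neural genes 7 rose, 3 fell and 9 did not pass (median 0.35), Olig2 by 1.73 and Tubb3 by 1.59, with Lhx2 at 0.36 without passing (camera Benjamini-Hochberg adjusted p = 0.028, adjusted p = 0.256 with an estimated correlation). Of 25 other developmental transcription factors 13 rose, 2 fell and 10 did not pass (median 1.08), Six2 by 3.83 and Tbx18 by 2.55 (camera Benjamini-Hochberg adjusted p = 0.0279, adjusted p = 0.284 with an estimated correlation, and 0.135 with a mean of at least 2 CPM). Eomes and Tdgf1 lie on chromosome 9 between 110 and 120 Mb, where the medians of the rescue libraries over 48 genes were 0.66, 0.62 and 0.59 against WT. Counts adjusted over the list alone were otherwise the same.

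A further 5 lists were called by camera in rescue against WT with the preset correlation alone, and differences between lists were not tested. Of 30 Hox genes 13 rose, 2 fell and 15 did not pass, with a median of 0.99, or 0.68 with Hoxd10 (6 counts against 0) at the bound that 3 counts give. Hoxc12 rose by 2.46, while Hoxb13 fell from 8.96 ± 0.909 to 2.16 ± 0.142 CPM (SD, n = 3). Of 22 germline genes 12 fell (13 adjusted over the list alone), 4 rose (5 adjusted over the list alone) and 6 did not pass (median -0.66), with the meiotic gene Hormad1, on chromosome 3 (median -0.41), at -1.98 and Smc1b at -1.51. Of 28 imprinted genes 11 fell, 7 rose and 10 did not pass (median -0.15), the neighbouring transcripts Meg3 at -2.57 and Rian at -2.48. Of 20 PRC1 genes 10 rose, 2 fell and 8 did not pass (median 0.17), Kdm2b by 0.59 and Cbx2 by 0.55. Of 9 H3K27 demethylase, acetyltransferase and other writer genes 7 rose (8 adjusted over the list alone), 0 fell and 2 did not pass (median 0.40), Crebbp by 0.88, Setd2 by 0.82 and Kdm6b by 0.70, Setd2 lying on chromosome 9 between 110 and 120 Mb where the rescue libraries stood at 0.66, 0.62 and 0.59 as a whole. Camera gave Benjamini-Hochberg adjusted p = 0.032 for germline genes and 0.0335 for each of the other 4 lists. With an estimated correlation the adjusted p was 0.147 for Hox, 0.147 for germline, 0.181 for imprinted, 0.165 for PRC1 and 0.478 for the demethylase list. The calls were also lost without dKO replicate 3 for Hox (adjusted p = 0.0962), imprinted (0.0962) and PRC1 genes (0.0583), without rescue replicate 1 for imprinted genes (0.0583) and without WT replicate 2 for the demethylase list (0.0515), and without chromosomes 3 and 14 for Hox (0.0523), germline (0.056) and PRC1 genes (0.0607). A mean of at least 2 CPM ended the calls of imprinted genes (0.0546) and of the demethylase list (0.0539), and no filter that of imprinted genes (0.102). Adjusted over the list alone, the other counts were the same.

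The remaining lists were not called in rescue against WT. Of 6 PRC2 core genes 3 rose, 2 fell and 1, Rbbp4 at -0.10, did not pass (camera Benjamini-Hochberg adjusted p = 0.312). The others were PRC2 accessory genes (4 higher, 1 lower, 3 not passing, 0.536), formative genes (6, 4 and 1, 0.254), endoderm genes (7, 3 and 7, 0.204), trophoblast genes (4, 3 and 6, 0.669), fibroblast markers (3, 1 and 6, 0.206), CDK inhibitors and p53 targets (1, 9 and 5, 0.0649), stress genes (7, 4 and 5, 0.425) and housekeeping genes (4, 1 and 9, 0.536). Cdh2 rose by 2.71, Foxd3 by 1.82, Sox17 by 2.34, Col4a1 by 1.55 and Fbn1 by 2.12, while Vim stood at -1.36, Krt7 at -1.69, Zmat3 on chromosome 3 (median -0.41) at -0.997, Gadd45a at -1.44 and Sdha at -0.46, all lower, and Aebp2 stood at -0.07 without passing. The CDK and p53 list was called without dKO replicate 3 (0.0481) and with no filter (0.0179), and the formative list without chromosomes 3 and 14 (0.0117). For stress genes the median was 0.20 and the mean -0.09, and for PRC2 core genes the median was 0.04 and the mean -0.46, with camera pointing down. Counts adjusted over the list alone were the same for these lists.

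Medians per chromosome were taken to look for gains or losses of large segments. In rescue against WT the median log2 fold change was -0.84 over 465 genes of chromosome 14 and -0.41 over 651 genes of chromosome 3, while every other autosome lay within 0.10 of 0. The 3 rescue libraries stood at -0.82, -0.85 and -0.83 for chromosome 14 and at -0.44 each for chromosome 3. On chromosome 14 the rescue libraries lay between -0.17 and 0.08 in the 10 Mb bins up to 30 Mb and between -0.78 and -1.42 in every bin beyond, of which those from 80 Mb on hold 3 to 14 genes each. dKO replicate 3 stood at -0.42 for chromosome 3, where dKO replicates 1 and 2 stood at 0.02 and 0.01, and at -0.29 for chromosome 14, where they stood at -0.09 each. In that library the chromosome 14 bins from 40 to 100 Mb lay between -0.28 and -0.52. In rescue against dKO the median was -0.43 for chromosome 3 and -0.79 for chromosome 14. Without dKO replicate 3 the first was -0.60. In dKO against WT it was -0.03 for chromosome 3, or 0.14 without dKO replicate 3, and -0.06 for chromosome 14. Without the genes of both chromosomes, 4433 genes rose and 4096 fell in dKO against WT, 4222 and 4866 in rescue against dKO, and 3484 and 3436 in rescue against WT. Without dKO replicate 3 the counts were 5074 and 4744, 4824 and 5768, and 4321 and 4389.

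**Figure D4:**
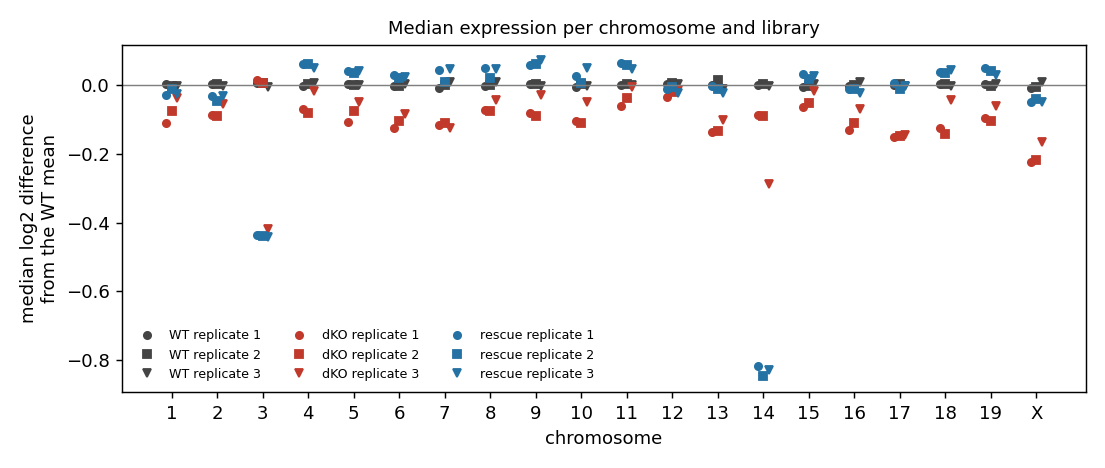
Median log2 difference from the WT mean over the genes of each chromosome with a mean of at least 5 CPM, per library (colour, group; shape, replicate). The 3 rescue libraries lie at -0.82 to -0.85 on chromosome 14 and at -0.44 on chromosome 3, where dKO replicate 3 lies at -0.42.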

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

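All alternatives here were chosen before the data were examined, except the one without the genes of chromosomes 3 and 14, which was chosen after those chromosomes had been seen. Requiring over 2-fold beside the adjusted p lowers every count by construction: to 2707 genes higher and 621 lower in dKO than WT, 712 and 2820 in rescue against dKO, and 910 and 919 in rescue against WT. The overlaps became 2054 and 314 genes that moved back, and 788 between rescue and WT in the direction of the dKO change, from 3494. Of 20 gene lists tested, camera called 9 in dKO against WT and 11 in each of the other comparisons, and 4, 3 and 0 with an estimated correlation. By fry, which does not compare a list with other genes, it was 16, 20 and 18. Against random lists matched on mean expression the median of Suz12-peak genes in rescue against WT, 0.058, lay at percentile 100, where camera had not called it, and the cause was not tested.

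With 1 library left out at a time, the counts ranged from 4477 to 5074 higher and 3894 to 4744 lower in dKO than WT, 4148 to 4824 and 5017 to 5768 in rescue against dKO, and 3159 to 4321 and 3298 to 4389 in rescue against WT. The overlaps ranged from 3445 to 4062, 2527 to 3247 and 2825 to 3782. The highest of each of these ranges came without dKO replicate 3. Odds ratios of Suz12-peak genes ranged from 4.10 to 4.28 (higher in dKO) and 0.339 to 0.359 (lower), their medians from 0.55 to 0.64, -0.61 to -0.55 and 0.04 to 0.08, and lists called from 9 to 10, 8 to 12 and 9 to 11. Other alternatives moved the odds ratios further, to 3.425 and 0.447 matched on mean expression and to 5.158 and 0.282 with peaks above the median width. The median in dKO against WT was 0.382 with a mean of at least 2 CPM and 1.022 with peaks above the median width. Without the genes of chromosomes 3 and 14 the overlaps were 3446, 2692 and 3219, and 9, 10 and 9 lists were called.

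The median of chromosome 3 with 1 library left out ranged from -0.11 to 0.14 in dKO against WT (highest without dKO replicate 3), -0.60 to -0.35 in rescue against dKO and -0.42 to -0.39 in rescue against WT. For chromosome 14 it was -0.10 to -0.01, -0.86 to -0.76 and -0.85 to -0.81. With DESeq2 size factors chromosome 3 was -0.404 in rescue against dKO, and chromosome 14 was -0.761 there and -0.826 against WT. With a mean of at least 2 CPM, chromosome 14 was -0.797 in rescue against dKO and -0.856 against WT, and chromosome 3 was -0.434 against WT. These moved by more than the spread between replicates but kept their sign. With DESeq2 size factors the median over all tested genes moved from -0.044 to -0.02 in rescue against dKO and from 0.002 to 0.019 against WT. These are shifts of similar size to those of the chromosomes under that scaling. The cause of the moves with a mean of at least 2 CPM was not tested.

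For the named genes, 4889 results under alternatives kept their side of the threshold and, where called, their direction, 123 crossed it upwards and 12 downwards. For the lists these were 941, 35 and 44. In none was a called direction reversed, but 43 of 282 gene results and 47 of 60 list results changed their call under at least 1 alternative. The median over all genes moved by less than 0.1 under the other scalings (TMM -0.003, -0.044 and 0.002, upper quartile 0.075, -0.11 and 0.013). With upper-quartile factors 5359 genes rose and 3535 fell in dKO against WT, and 3907 and 5840 in rescue against dKO. Of those that fell in dKO, 2184 rose again. With DESeq2 size factors 4726 genes rose and 4451 fell in dKO against WT. DESeq2 gave no adjusted p for 2542, 2542 and 2905 genes in the 3 comparisons. Depth ran from 12457622 to 36009529 counts.

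Replicate numbers did not pair the samples: deviations from the group means correlated at -0.112 to 0.201 between libraries of the same number, and WT replicate 1 correlated at 0.186 with rescue replicate 2. With the replicate block all the same, the counts were 4750 and 4398, 4526 and 5391, and 3751 and 3861, the overlaps 3668, 2820 and 3475, and 10, 12 and 10 lists were called. With the block Eed in rescue against WT was no longer called (edgeR, Benjamini-Hochberg adjusted p = 0.0564), nor were imprinted genes there (0.0802), while trophoblast genes were called in dKO against WT (0.0141) and in rescue against dKO (0.0291).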

Other observations

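The tests of the rescue chromosomes, of a general shift and of copy number in dKO replicate 3, of leftover dKO cells and the counts of germline genes called lower, the limit on the mean of WT and rescue, the peak width classes and the other segments were chosen only after the result was seen, and so was the number of random assignments of the 9 libraries.

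Genes under wide Suz12 peaks gained more in dKO than genes under narrow ones. The median log2 fold change against WT was 0.02 over 96 genes with peaks under 500 bp, 0.24 over 1544 genes at 500 to 1000 bp, 0.84 over 1323 genes at 1000 to 2000 bp, 1.12 over 577 genes at 2000 to 4000 bp and 2.28 over 152 genes from 4000 bp. The share called higher was 29.2%, 48.5%, 64.2%, 68.5% and 80.9%. In rescue against WT the medians were 0.04, -0.01, 0.08, 0.17 and 0.66. After the peak over Hoxb5 to Hoxb7, the widest peaks lay over Ebf3 (15526 bp), Tfap2a (14382 bp) and Sp9 (13431 bp), which encode transcription factors of development. The trend was not tested.

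In the 3 rescue libraries expression was lower over chromosome 14 from 30 Mb on and over chromosome 3. Silencing of Polycomb targets is argued against by genes without a Suz12 peak, whose medians were -0.966 (283 genes) and -0.45 (460 genes), a few lowered genes by the 89.4% and 78.6% of genes below WT (46.9% on other autosomes), and scaling by the other autosomes, whose largest median was 0.096. Fewer copies of these chromosomes stays open as a hypothesis: the medians over genes of low, middle and high expression were -0.66, -0.982 and -0.969 for chromosome 14 and -0.217 (quartiles -0.80 to 0.56), -0.467 and -0.474 for chromosome 3. RNA counts cannot show DNA copies.

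In dKO replicate 3 alone among the dKO libraries, expression was lower over chromosome 3 and part of chromosome 14. RNA of rescue cells as the whole cause is argued against by 744 genes over 4-fold lower in rescue than in dKO on other autosomes, whose median implied share of rescue RNA was 0.196 (quartiles 0.018 to 0.375), where chromosome 3 needs 0.95 and chromosome 14 needs 0.421. A general shift towards the rescue expression stays open, since deviations of this library correlated with rescue against WT at 0.443 on the other autosomes. So do fewer copies of chromosome 3 in part of the cells, with medians of -0.485, -0.471 and -0.424 over genes of low, middle and high expression.

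In rescue against WT 13 of 30 Hox genes were called higher (2 lower) and 12 of 22 germline genes lower (4 higher), with medians of 0.99 and -0.66, and neither list was called with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.147 each). Location on chromosomes 3 and 14 is argued against by the 18 germline genes elsewhere, with a median of -0.656 (quartiles -1.07 to 0.28), 10 called lower and 4 higher, though the list as a whole was not called without those chromosomes (camera, Benjamini-Hochberg adjusted p = 0.056). Low counts are argued against by the 17 germline genes of at least 2 CPM in WT, the same 17 that have a mean of WT and rescue of at least 2 CPM, with a median of -0.809 (quartiles -1.39 to 0.04), 10 called lower and 4 higher. dKO cells left in the rescue cultures cannot be told apart: the median share of the dKO gain kept was -0.0242 for germline genes (quartiles -0.226 to 0.0195, 11 of 18 below 0) and 0.073 for Hox genes (0.0032 to 0.314, 7 of 28 below 0), so the quartiles overlap. A difference between the 2 lists was not tested, and an effect of EZH2 stays open as untested.

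Each comparison of 3 libraries against 3 has 10 splits, too few for a share under 0.05. All splits but the real one put libraries of both groups on each side. The group difference then adds to the spread within a side, so few genes called there follow from the design. Part of the difference also stays between the sides. The values below therefore cannot show what chance alone gives, for genes, lists or Suz12-peak medians. Real and highest other values were 9151 and 0 genes called in dKO against WT, 9941 and 0 in rescue against dKO, and 7653 and 17 in rescue against WT, each reached by 1 split, the real one. For lists called they were 9 and 10 (5 splits as large), 11 and 9 (1 split) and 11 and 5 (1 split). For the size of the Suz12-peak median they were 0.57 and 0.204, 0.571 and 0.21, and 0.058 and 0.05 (1 split each).

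For the overlaps, 100 assignments of the 9 libraries were used, the real one and random others. Only the real one gave as many genes that rose in dKO and fell in rescue (3715, highest other 423). The same held for genes that fell and rose (2834, highest other 477). Renamings of the real groups were left out, though exchanging the names WT and rescue gives the same 2 counts. Every other assignment mixes libraries of different groups. These draws therefore cannot exclude chance for the 2 overlaps, nor gauge their size. For the 3494 genes between rescue and WT in the direction of the dKO change, 3 of 100 assignments gave as many, but 3 of 60 among the first 60, a share at the limit of 0.05. The number had been raised from 60 to 100, and renamings of the real groups left out, after an earlier draw of 60 had ended at that limit, so chance is not treated as excluded there either. An assignment gave 4935, above the real count, and the cause was not tested.

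Over the first 10 Mb of chromosome X (33 genes) the median difference from WT was 0.75, 0.81 and 0.71 in the dKO libraries and 0.95, 0.99 and 0.96 in the rescue libraries. On chromosome 9 the rescue libraries stood at 0.66, 0.62 and 0.59 from 110 to 120 Mb (48 genes) and at 0.45, 0.47 and 0.49 from 120 to 130 Mb (31 genes). On chromosome 18 from 80 to 90 Mb (18 genes) the dKO libraries stood at 0.34, 0.40 and 0.53 and the rescue libraries at 0.71, 0.70 and 0.73.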
